A study of Mus musculus with 2 samples.

How the data were processed

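The series holds total RNA-seq of mouse heart with ribosomal RNA reduced, from 2 libraries, each made from 300 ng of RNA purified with a Norgen animal tissue kit, per the labels. Both libraries belong to 1 group, male B6CASTF1/J hearts at 2 months, and the replicate numbers were taken from the labels. No second group was given, so no contrast between conditions was made.

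For each library the authors deposited a gene table, a transcript table quantified from an aligned file, and a second transcript table quantified directly from reads, per the deposited descriptions of the files. The genome build was mm10 and the annotation GENCODE M21, per the same descriptions. The aligner, the quantifiers and their versions are not given in the sources used here; the column names of the first 2 tables are those RSEM writes, and those of the third are the ones kallisto writes. The gene table holds expected counts, TPM, posterior mean TPM and FPKM as deposited by the authors, per the file headers. The second transcript table holds estimated counts and TPM as deposited by the authors, per the file headers. Whether counting used strand is not stated in the sources used here, so genes that overlap on opposite strands, such as Mhrt and Myh7, may share reads.

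Gene symbols, biotypes and coordinates came from the GENCODE M21 annotation, in which all 55536 Ensembl gene identifiers of the gene table were found. A further 26248 entries with numeric identifiers held 3 and 2 expected counts in replicates 1 and 2, and phiX174 held 0, so these were left out. The 96 spike-ins were left out of gene totals. A nuclear gene was called a copy of a mitochondrial gene where at least 50% of the 31-base words of a transcript occurred in mitochondrial transcripts. Where a symbol had several identifiers, the one with the most counts was used. Of 677 symbols in the gene lists, 675 were found, 2 of them (Ctgf and Cyr61) under their newer symbols Ccn2 and Ccn1, and Norad and Rn45s were not. The transcript tables shared 141767 transcripts, and 95 transcripts of unplaced scaffolds were only in the first.

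Levels were given as the mean and SD of TPM over the 2 mice. A gene was counted as detected at 1 TPM in both mice. Expected counts were rounded to whole numbers for edgeR 4.0.16 (R 4.3.3), which gave TMM scaling factors and the common dispersion under an intercept-only model after filterByExpr; the biological coefficient of variation is its square root. The log2 ratio of effective library sizes was 0.23. Ratios between mice are replicate 2 over replicate 1 of TMM-scaled counts with a prior count of 0.5, for genes with a mean expected count of at least 50, and 2-fold was the threshold. Counting intervals are exact Clopper-Pearson intervals at 95%, and shares of counts have Wilson intervals; both, and the floor of 3 counts, cover counting error only, since the counts carry no molecular identifiers. Each list's median ratio was placed among 10000 random lists of the same size matched on mean expression in 20 bins. Each list's median TPM was placed among 10000 random lists of detected genes. The statistics were tested on simulated counts of 12470 genes. All of 100 genes changed 4-fold were called, 1.01% of 99 genes changed 1.5-fold were called, and 1 unchanged gene was called. The simulation drew the counts of each gene independently, with no reads shared between genes, so errors of the quantifiers were not tested. A simulated coefficient of variation of 10% was estimated at 10.0% with no changed gene and at 13.3% with the changed genes, so the estimate includes the genes that differ. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

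The gene lists, paralog pairs, isoform genes and the rule for named genes were set before the data were examined. The rule named the 20 nuclear protein-coding genes highest in TPM, up to 4 members of each list with the highest TPM, list members near 0, the genes of the paralog pairs, the 10 largest ratios between mice in each direction, the isoform genes whose dominant transcript differed, the 5 isoform genes highest in TPM, and the 10 genes farthest apart between quantifiers at 10 TPM or more in the gene table. Of 24 paralog pairs set beforehand, 1 is not reported here, nor are several members of the gene lists and isoform genes that the rule would name. Other list members are named as examples, chosen after their values were seen. Alternatives were the second transcript table, posterior mean TPM, FPKM, TPM rescaled to nuclear protein-coding genes, DESeq2 1.42.0 size factors, total count and spike-in scaling, other thresholds, pseudocounts and priors, and leaving out each mouse. Dominant transcripts were also compared in genes with 10 TPM and where the dominant one was at least 1.5 times the next. In addition, 3 lists of platelet, neutrophil and further adipocyte genes were written after the differences between the mice had been seen.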

Results

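Total RNA depleted of ribosomal RNA was sequenced from the hearts of 2 male B6CASTF1/J mice aged 2 months. These animals are F1 hybrids of a B6 and a CAST parent, and were obtained from The Jackson Laboratory. The labels give 1 group of 2 biological replicates, taken here as 2 mice, with 1 library each and no treatment or second tissue. The labels give both the same donor entry but number the males and the tissue samples separately, so that they are 2 animals is a reading of the labels. The results are therefore expression levels with their spread (SD, n = 2 mice), ratios of genes within a library, and the differences between the 2 hearts. Expected counts summed to 39177981 in replicate 1 and 44544839 in replicate 2.

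Mitochondrial transcripts and nuclear protein-coding genes took similar shares of the gene-table TPM in these hearts. Mitochondrial genes together with their copies in the nuclear genome held 40.7 ± 0.898% of TPM, and the 22015 nuclear protein-coding genes held 39.04 ± 0.542%. The 2 mitochondrial ribosomal RNAs alone held 18.3 ± 0.208%, led by mt-Rnr2 at 119427 ± 1153 TPM. The mitochondrial protein genes held 14.3 ± 0.836%, with mt-Co1, a subunit of cytochrome c oxidase, at 37476 ± 806 TPM. A further 8.15 ± 0.147% lay on 7 nuclear copies of mitochondrial genes, whose reads cannot be told apart from mitochondrial reads, so levels of single mitochondrial genes are uncertain. The 7SL RNA genes Rn7s1 and Rn7s2, the RNA of the signal recognition particle, held 13.1 ± 0.505%, and Rn7sk held 1.51 ± 0.208%. These RNAs are short, and they took 2.08 ± 0.0828% and 0.277 ± 0.0379% of expected counts, while the nuclear copies took 3.64 ± 0.0834%. In expected counts, which are not corrected for length, nuclear protein-coding genes took 60.3 ± 1.06% and mitochondrial genes with their copies 32.7 ± 0.553%. The shares were not computed with the second quantifier and depend on the quantifier. With it Rn7s1, Rn7s2, Rn7sk and the nuclear copy Gm10925 had means under 1 TPM.

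Of 55536 annotated genes in the gene table, 11936 reached 1 TPM in both mice, among them 10970 of 22028 protein-coding genes, 139 lincRNAs and 362 processed pseudogenes. The most abundant nuclear protein-coding genes were those of the contractile apparatus, calcium cycling, oxygen transport and oxidative metabolism. Myl2 (ENSMUSG00000013936.12; mm10 chromosome 5, 122100951 to 122113472), the ventricular regulatory light chain of myosin, stood first at 8071 ± 621 TPM. It was followed by Myh6 (ENSMUSG00000040752.16; chromosome 14, 54941921 to 54966927), the alpha heavy chain of myosin, at 7699 ± 573 TPM and by Mb (ENSMUSG00000018893.15; chromosome 15, 77015487 to 77050670), which encodes myoglobin, at 7679 ± 148 TPM. Atp2a2, the calcium pump of the sarcoplasmic reticulum, reached 4970 ± 157 TPM and its inhibitor Pln 2621 ± 169 TPM. Myl3 (4136 ± 187 TPM), Tnni3 (4047 ± 242), Tpm1 (3839 ± 196), Actc1 (3658 ± 126), Tnnt2 (3423 ± 199.8) and Tnnc1 (2027 ± 119) completed the sarcomere genes among the first 20. The ATP synthase subunit Atp5b stood at 3375 ± 190 TPM, the fatty acid binding protein Fabp3 at 2326 ± 88.6, the ADP/ATP carrier Slc25a4 at 1989 ± 120.0, Cox4i1 at 1840 ± 88.9, Cox6b1 at 1695 ± 148 and lipoprotein lipase (Lpl) at 1635 ± 54.5. The hemoglobin genes Hbb-bs (4864 ± 3745 TPM), Hba-a1 (4085 ± 2876) and Hba-a2 (3906 ± 2827) were also among the first 20, with an SD of over 0.5 of their mean. The 20 genes together took 19.96 ± 1.82% of nuclear protein-coding TPM. With the second quantifier 16 of the 20 stayed among the first 20, and Mb, Hba-a1 and Hbb-bs stood above Myh6.

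**Figure D1:**
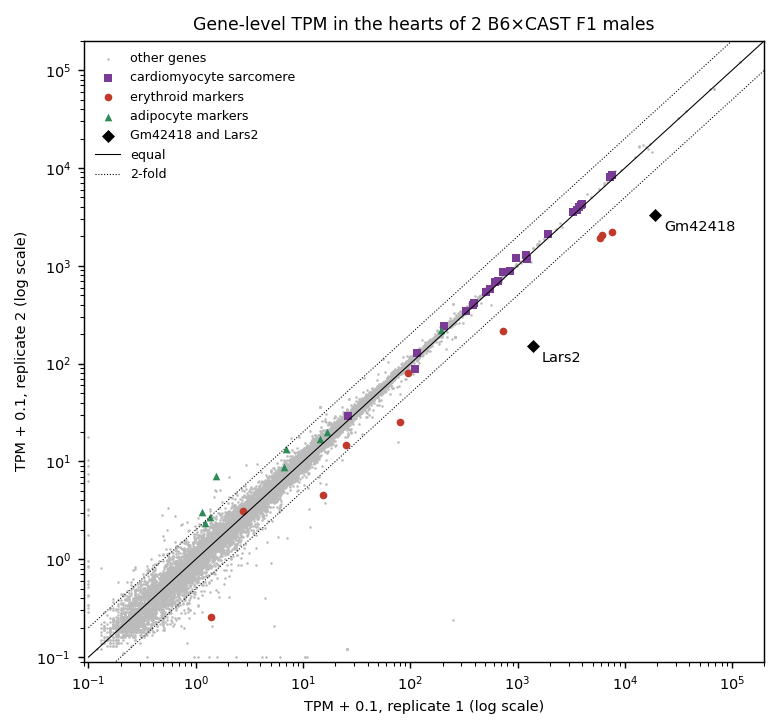
Gene-level TPM + 0.1 of replicate 1 (x axis) against replicate 2 (y axis), both on log scales, for genes with a mean expected count of at least 10; the solid line marks equal values and the dotted lines a 2-fold difference. Sarcomere genes lie along the line, erythroid genes other than Car2 lie below it with Gm42418 and Lars2, and adipocyte genes lie above it.

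The cardiac member of nearly every fixed paralog pair was the more abundant one. In 22 of 23 pairs the gene named first, for most of them the form of adult heart muscle, was higher in both mice. Myh6 exceeded Myh7, the beta heavy chain of the fetal ventricle and slow muscle, by 9.73 ± 0.411-fold, which was 4.52-fold with the second quantifier and 23.5-fold in expected counts. Actc1 exceeded the skeletal actin Acta1 by 37.6 ± 7.23-fold. Cardiac troponin I (Tnni3) stood at 4047 ± 242 TPM against 0.345 ± 0.0354 for the slow skeletal form Tnni1, and cardiac troponin C (Tnnc1) at 2027 ± 119 against 0.150 ± 0.0566 for the fast form Tnnc2. Tnnt2 exceeded Tnnt1 by 532 ± 90.9-fold. The log2 ratio of Atp2a2 to the fast-muscle pump Atp2a1 was 13.49 ± 0.17, that of Ryr2 to Ryr1 was 13.17 ± 0.71, and that of Casq2 to Casq1 was 7.44 ± 0.30. Ryr1, Atp2a1, Tnni1 and Tnnc2 lay under 0.5 TPM, so the size of those ratios rests on few counts. With the second quantifier Tnni3 exceeded Tnni1 by a log2 ratio of 12.92 instead of 13.52, and Tnnc1 exceeded Tnnc2 by 13.10 instead of 13.77. In expected counts the log2 ratios were 12.77 for Tnni3 to Tnni1, 14.38 for Ryr2 to Ryr1 and 8.16 for Casq2 to Casq1. The ventricular light chains outweighed the atrial ones, Myl2 over Myl7 by 39.1 ± 1.66-fold (65.0-fold with the second quantifier) and Myl3 over Myl4 by 17.3 ± 0.968-fold. The natriuretic peptide gene Nppa exceeded Nppb by 14.8 ± 1.07-fold.

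Enzyme pairs had the same order. Muscle creatine kinase (Ckm) exceeded the brain form Ckb by 57.8 ± 4.56-fold, the insulin-responsive glucose transporter Slc2a4 exceeded Slc2a1 by 27.4 ± 4.57-fold, and Eno3 exceeded Eno1 by 14.8 ± 0.0637-fold. The muscle carnitine palmitoyltransferase Cpt1b exceeded Cpt1a by 10.6 ± 0.159-fold, and Ldhb, the lactate dehydrogenase subunit of heart, exceeded Ldha by 4.27 ± 0.159-fold. The muscle forms of the cytochrome c oxidase subunits were above the ubiquitous ones, by 12.0 ± 0.169-fold for Cox6a2 over Cox6a1, 7.81 ± 0.209-fold for Cox8b over Cox8a and 3.03 ± 0.0291-fold for Cox7a1 over Cox7a2. Pgam2 exceeded Pgam1 by 6.20 ± 0.140-fold, Hk2 exceeded Hk1 by 3.16 ± 0.176-fold, and Ppara, a regulator of fatty acid oxidation, exceeded Pparg by 5.43 ± 1.27-fold. With the second quantifier the fold of Cox7a1 over Cox7a2 was 1.94 and that of Ppara over Pparg 3.43. In expected counts that of Cox7a1 over Cox7a2 was 1.76, that of Cox8b over Cox8a 4.52 and that of Pgam2 over Pgam1 2.76. Hba-a1 was below Hbb-bs in both mice, with a log2 ratio of -0.20 ± 0.13, which turned to 0.10 with the second quantifier. With 2 mice the smallest 2-sided exact paired p is 0.5, so no p is given for these ratios.

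**Figure D2:**
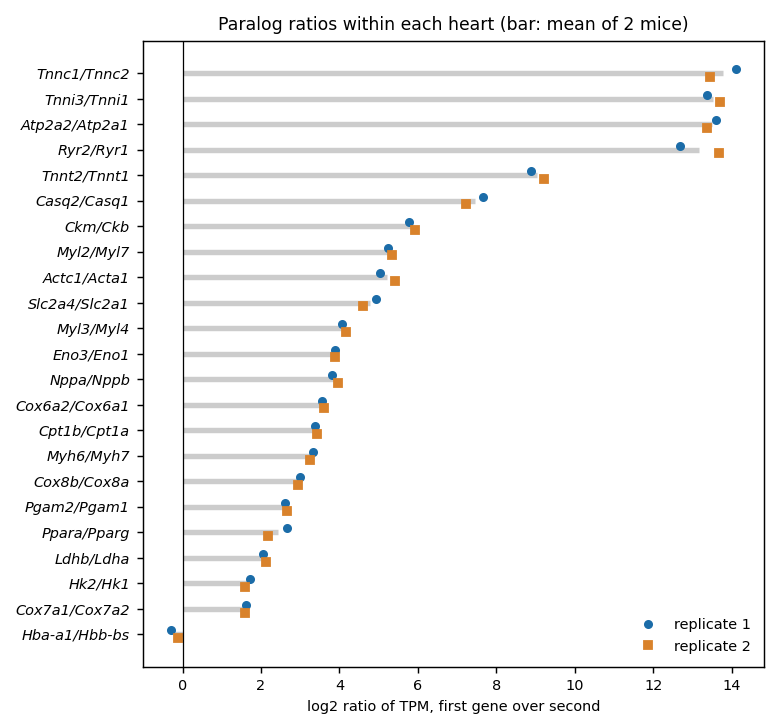
The log2 ratio of TPM of the first over the second gene of 23 fixed paralog pairs (x axis), with the value of each mouse as a point and the mean as a bar. The 2 points of each pair lie on the same side of 0, and only Hba-a1/Hbb-bs lies below it.

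Gene lists of contraction and energy metabolism stood far above the bulk of detected genes. The 24 sarcomere genes had a median of 831 ± 55.8 TPM and were all above 1 TPM, and the lowest of them, Tnni3k, stood at 27.7 ± 1.93. Mitochondrially encoded proteins had a median of 8750 ± 952 TPM (mt-Co1, mt-Cytb, mt-Atp6 and mt-Co3 leading), nuclear-encoded respiratory chain genes 650 ± 31.9 (Atp5b, Cox4i1, Cox6b1 and Atp5a1), the tricarboxylic acid cycle 355 ± 15.8 (Mdh1, Idh2 and Ogdh among the highest) and fatty acid uptake and oxidation 308 ± 20.7 (Fabp3, Lpl, Hadhb and Cd36). Glucose uptake and glycolysis had a median of 192 ± 11.9 TPM, led by Gapdh at 1582 ± 99.0 and Aldoa at 1461 ± 76.9, and ketone and pyruvate metabolism 150 ± 7.46, led by Oxct1 at 571 ± 18.2 and Pdha1 at 449 ± 26.1. Within these lists Cpt1a (20.6 ± 0.530 TPM), Slc2a1 (6.37 ± 1.23), Pdk3 (1.17 ± 0.0212) and Aldoc (0.255 ± 0.0354) were low. Calcium handling genes had a median of 156 ± 9.31 TPM, with S100a1 at 408 ± 3.25 and Ryr2 at 391 ± 0.537 after Atp2a2 and Pln, and Fkbp1b at 0.350 ± 0.226. Cytosolic ribosomal protein genes had a median of 211 ± 19.3 TPM, led by Rplp1 at 597 ± 44.1. Each of these medians lay above all 10000 medians of random lists of the same size drawn from detected genes, and 19 of the 42 lists lay in the top 2.5% of them. These percentiles describe the 2 libraries and are no test.

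Regulators and membrane proteins of heart muscle were present at moderate levels. The 16 cardiac transcription factors were all above 1 TPM in both mice, with a median of 29.5 ± 0.827; Esrra (66.5 ± 3.67), Mef2a (48.3 ± 4.51), Mef2d (47.2 ± 3.16) and Ppargc1a (46.3 ± 4.42) were highest, and Gata4 stood at 38.9 ± 1.82 and Nkx2-5 at 35.4 ± 2.15. Ion channel and gap junction genes had a median of 16.2 ± 0.817 TPM, with Gja1, the main connexin of working muscle, at 129 ± 11.4 and Kcnip2, a subunit of potassium channels, at 74.3 ± 5.01. Atrial transcripts were measured beside ventricular ones. Nppa stood at 698 ± 0.643 TPM, Myl4 at 239 ± 2.56, Myl7 at 206 ± 7.14 and Sln at 29.8 ± 1.96, while the ventricular genes Hopx and Lbh stood at 140 ± 10.03 and 125 ± 15.2. Conduction system genes had a median of 1.995 ± 0.00707 TPM; Smoc2 (13.5 ± 0.707), Irx3 (12.1 ± 0.219), Gja5 (5.11 ± 0.488) and Cacna1g (4.59 ± 0.134) were highest, the pacemaker channel Hcn4 stood at 2.995 ± 0.177, and Isl1 stood at 0.0800 ± 0.0424.

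Lists of the other cell types of heart tissue had medians below those of contraction and energy metabolism. Vascular endothelial genes had a median of 35.3 ± 1.10 TPM and were all above 1 TPM, with Fabp4 at 271 ± 8.10, Aqp1 at 161 ± 15.5, Ly6c1 at 102 ± 3.78 and Egfl7 at 47.6 ± 7.18. Extracellular matrix genes had a median of 21.2 ± 0.0778 TPM, led by Lamb2, Sparc, Col4a1 and Bgn, of which Lamb2 stood at 134 ± 5.28. Fibroblast genes had a median of 9.91 ± 0.0354 TPM, with Gsn at 335 ± 2.12, Dcn at 145 ± 11.6 and the fibroblast regulator Tcf21 at 3.59 ± 0.127. Pericyte and smooth muscle genes had a median of 11.6 ± 1.39 TPM, led by Des, which cardiomyocytes also make, then Rgs5 at 106 ± 4.95, Abcc9 at 88.7 ± 1.70 and Smtn at 52.3 ± 0.417. Macrophage and monocyte genes had a median of 4.65 ± 0.148 TPM, with Lyz2 at 59.4 ± 3.30 and the complement genes C1qb, C1qa and C1qc at 18.8 ± 3.11, 18.1 ± 1.06 and 15.2 ± 0.997. Endocardial and lymphatic genes (Ccl21a, Prox1, Npr3 and Cytl1 leading) had a median of 9.51 ± 1.72 TPM, and epicardial and mesothelial genes (Upk3b, Msln, Krt19 and Muc16) 1.995 ± 0.0495. Schwann cell and neuronal genes had a median of 0.720 ± 0.0849 TPM, and only 6 of 15 reached 1 TPM in both mice (Pmp22, Uchl1, Cnp and Mbp leading). Lymphocyte genes had a median of 0.283 ± 0.166 TPM, with Ighm, Igkc, Ptprc and Cd79b at 5 ± 1.34, 3.15 ± 1.66, 2.65 ± 0.580 and 1.21 ± 0.757.

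Genes of neighbouring and unrelated tissues were mostly near 0. None of 9 lung epithelium genes, 12 liver genes and 9 thymocyte genes reached 1 TPM in both mice. The surfactant genes Sftpc, Sftpa1 and Sftpd and the albumin gene Alb had a TPM of 0 in both libraries, as did Rag2, Ptcra and Dntt. The highest members were Cyp2f2 at 0.315 ± 0.120 TPM, Apoa2 at 0.665 ± 0.247 and Cd1d1 at 0.865 ± 0.0212. Of the fast skeletal muscle list, Ckm stood at 1465 ± 87.7 TPM, Myl1 at 10.02 ± 1.94, Mybpc2 at 6.15 ± 0.354 and Casq1 at 1.82 ± 0.445, while the fast myosin genes Myh2, Myh4 and Myh1 stood at 0, 0 and 0.00500 ± 0.00707. Among 12 testis and brain genes, 10 lay below 0.1 TPM in both mice, and the others were Slc17a7, a vesicular glutamate transporter, at 9.84 ± 0.728 and Gad1 at 0.245 ± 0.219. The Y-linked genes Ddx3y (25.5 ± 0.467 TPM), Eif2s3y (21.4 ± 2.33), Uty (8.33 ± 0.318) and Kdm5d (3.79 ± 0.177) were present, and Zfy1, Zfy2, Sry and Usp9y were at 0. Xist, the RNA of the inactive X chromosome, stood at 0.01 TPM in both mice. Proliferation genes had a median of 0.235 ± 0.0212 TPM, with Mki67 at 0.380 ± 0.0141 and Pcna at 14.3 ± 1.40.

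**Figure D3:**
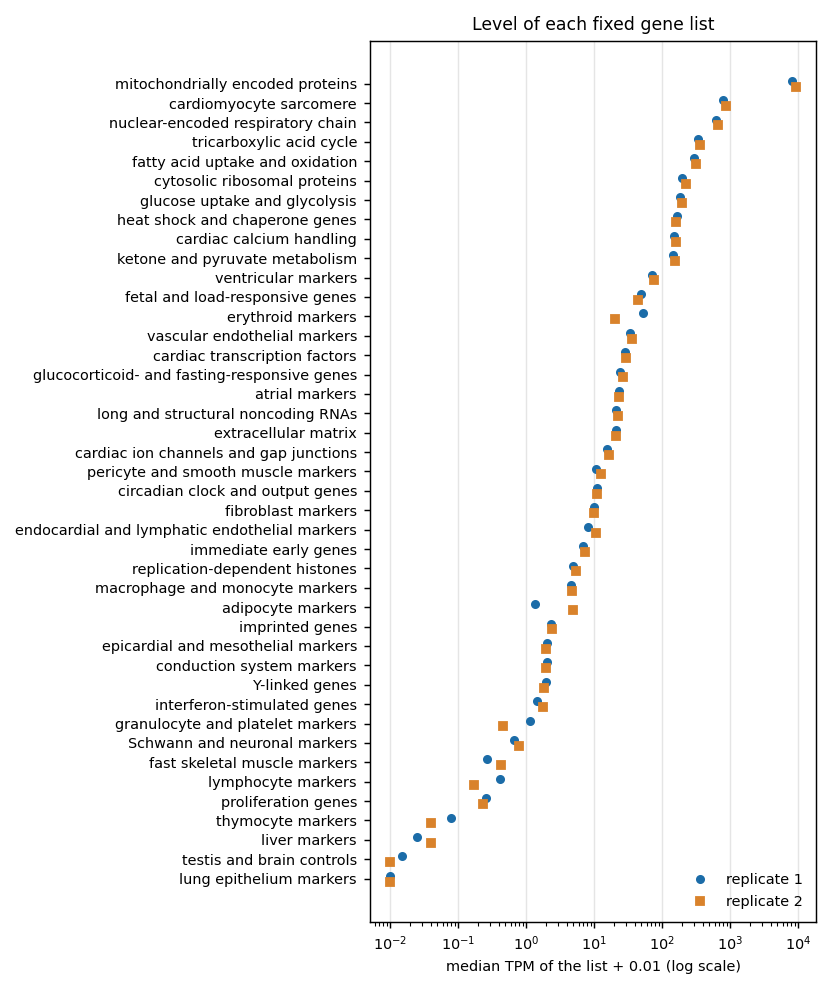
Median TPM + 0.01 of the measured members of each of 42 fixed gene lists (x axis, log scale), with a point per mouse. Mitochondrially encoded proteins stand highest at a median of 8750 TPM, and lung epithelium genes lowest at 0.

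Genes that respond to load, hormones, time of day or handling were measured as they stood at collection. Fetal and load-responsive genes had a median of 47.4 ± 3.22 TPM, with Myh7 at 793 ± 92.4, Nppa at 698 ± 0.643, Ankrd1 at 215 ± 5.24, Nppb at 47.2 ± 3.44 and Gdf15 at 0.535 ± 0.134. Immediate early genes had a median of 7.11 ± 0.357 TPM, with Jund at 46.8 ± 0.389, Klf2 at 24.5 ± 6.58, Dusp1 at 24.3 ± 1.01, Ccn1 at 20.1 ± 1.39, Fos at 2.19 in both mice and Egr1 at 2.07 ± 0.332. The clock output genes Usp2, Tef and Dbp stood at 73.5 ± 7.98, 47.6 ± 1.77 and 47.5 ± 5.64 TPM, Nr1d1 at 44.2 ± 2.16 and the clock gene Arntl at 3.58 ± 1.17. Glucocorticoid- and fasting-responsive genes were led by the metallothionein Mt1 at 170 ± 2.94 TPM, Pdk4 at 111 ± 12.6, Zbtb16 at 58.4 ± 1.67 and Tsc22d3 at 46.4 ± 10.05. Chaperones were led by Cryab at 1242 ± 53.2 TPM, Hspa8 at 587 ± 4.87, Hspb7 at 556 ± 25.2 and Hsp90ab1 at 495 ± 15.8, whereas the stress-induced Hspa1a and Hspa1b stood at 1.39 ± 0.148 and 1.04 ± 0.120. Interferon-stimulated genes had a median of 1.59 ± 0.230 TPM, with Ifi27 at 24.6 ± 2.503, Bst2 at 6.63 ± 0.424 and Gbp2 at 5.08 ± 1.499.

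Levels of histone genes, noncoding RNAs and imprinted genes were also measured, but whether their RNAs carried poly(A) tails was not. Replication-dependent histone genes, whose messages mostly lack poly(A) tails, had a median of 5.14 ± 0.325 TPM, with Hist1h4h at 91.5 ± 0.269, Hist1h1c at 70.4 ± 0.721, Hist1h2bc at 31.4 ± 1.77 and Hist1h4d at 19.2 ± 0.863. The RNA subunit of RNase P, Rpph1, stood at 2550 ± 95.5 TPM, the nuclear RNAs Malat1 and Neat1 at 1219 ± 159 and 79.8 ± 13.7, and Mhrt, an RNA transcribed opposite Myh7, at 28.4 ± 0.728. Among 23 imprinted genes, Gnas led at 459 ± 20.3 TPM, followed by Igf2r at 43.2 ± 1.98, Snrpn at 39.2 ± 1.41 and Igf2 at 28.4 ± 0.608, while Magel2, Rtl1 and Dlk1 lay under 0.1 TPM.

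The 2 hearts were close to each other. Across 12582 genes with at least 1 TPM in at least 1 mouse, Pearson's r of log2(TPM + 1) was 0.987 and Spearman's rho 0.985; genes are not independent replicates, so these describe the libraries. The biological coefficient of variation from edgeR was 6.63% over 15170 genes. Of 12453 genes with a mean expected count of at least 50, 99.4% were within 2-fold of each other.

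Blood genes, Lars2 and a lincRNA with ribosomal-like sequence were higher in replicate 1, and a few genes of adipocytes and the Nr4a family were higher in replicate 2. Of the 12453 genes, 46 were at least 2-fold higher in replicate 1 and 25 in replicate 2, and scaling on the spike-ins gave 31 and 43. The second quantifier gave the same direction at 2-fold or more for 33 and 13 of them, a check chosen after the data were seen, and turned the sign of 6, with Zc3h11a going from 1.29 to -1.81. Each mouse has 1 library, so these differences have no replicate check and no p, and the intervals given cover counting error only. The 25 genes higher in replicate 2 include the snoRNA genes Rnu3b1, Rnu3b2, Rnu3b3 and Rnu3b4. Each of these had 51.53 counts in replicate 1 and 147.93 in replicate 2, so they may not be separate differences. Hbb-bs stood at 7512 TPM in replicate 1 and 2215 in replicate 2, 3.52-fold higher in replicate 1 (log2 ratio of replicate 2 over replicate 1 -1.81, 95% exact counting interval -1.83 to -1.80). Hba-a1 was 3.11-fold, Hba-a2 3.21-fold and Hbb-bt 3.54-fold higher in replicate 1, and Alas2, the first enzyme of heme synthesis in red cells, 3.40-fold. Slc4a1, the anion exchanger of the red cell membrane, was 4.97-fold higher with 99 against 23 counts. Of the 10 erythroid genes with enough counts, 7 were at least 2-fold higher in replicate 1, and the median log2 ratio of the 10 was -1.72, below all 10000 matched random lists. Bpgm was 1.88-fold and Fech 1.21-fold higher in replicate 1, and for Car2 the log2 ratio of -0.24 had an interval of -0.60 to 0.11 that includes 0. The platelet genes Rgs18 (4.78-fold) and Ppbp (4.49-fold) were higher in replicate 1 as well, and the granulocyte and platelet list had a median log2 ratio of -0.92 with 6 of 6 tested members lower in replicate 2.

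Gm42418 and Lars2 had high levels and large differences. Gm42418, a lincRNA with ribosomal-like sequence, stood at 19073 TPM in replicate 1 and 3298 in replicate 2, 5.99-fold apart (log2 ratio -2.58, interval -2.59 to -2.58). Lars2, which encodes mitochondrial leucyl-tRNA synthetase, stood at 1385 and 152 TPM, 9.43-fold apart, and the ribosomal RNA feature CT010467.1 was 5.49-fold higher in replicate 1 with 530 against 113 counts. Chtf8 was 7.20-fold apart in expected counts, with 174 against 28.0, but its TPM was 3.45 and 2.95. The 4 largest ratios towards replicate 1 were those of Gm24497, Gm14760, Gm45837 and Gm6361, listed at under 1 count in replicate 2. Against a floor of 3 counts there, they were 282-fold, 48.8-fold, 47.3-fold and 42.6-fold higher in replicate 1. Their counting intervals reached log2 ratios of -7.84, -5.28, -5.25 and -5.09. Of these 4, only Gm14760 was 2-fold higher in replicate 1 with the second quantifier, and the log2 ratio of Gm45837 turned to 1.61. The snRNA genes Gm23444 and Gm23472 had the same TPM as Gm24497 in replicate 1, 252.55, and were higher in replicate 2. The ratio of Gm24497 may therefore reflect reads divided differently among these genes, which was not tested.

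Among genes higher in replicate 2, Ucp1, the uncoupling protein of brown fat, stood at 6.95 TPM against 1.43 in replicate 1 (log2 ratio 2.23, interval 1.86 to 2.63). Pck1 was at 6.88 against 1.96 TPM (1.86, interval 1.60 to 2.14), and Tgtp2, a GTPase induced by interferon gamma, at 2.65 against 0.540 TPM (2.37, interval 1.78 to 3.13). Gm43302 had 104.5 against 3.41 counts (4.53, interval 3.30 to 7.18), and Gm20503 had 92.5 against 23.6 (1.72, interval 1.04 to 2.42). Gm14440, Rpl30-ps9, Gm6565, Gm10335 and Gm45234 had no count in replicate 1. Against a floor of 3 counts there, they were 103-fold, 43.9-fold, 34.3-fold, 32.8-fold and 30.9-fold higher in replicate 2. The lower counting bounds of their log2 ratios were 6.38, 5.14, 4.78, 4.72 and 4.63. Of these 5, only Gm10335 was 2-fold higher in replicate 2 with the second quantifier. The orphan nuclear receptors Nr4a1, Nr4a2 and Nr4a3 had log2 ratios of 1.18, 1.55 and 1.42, and were the 3 immediate early genes at least 2-fold higher in replicate 2. The 9 adipocyte genes with enough counts all had log2 ratios above 0, with a median of 0.88, but only Ucp1 and Plin1, a coat protein of lipid droplets with 1.25, were at least 2-fold higher in replicate 2.

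Of 35 lists with at least 5 such genes, 16 had a median log2 ratio outside the middle 95% of matched random lists, where 1.75 would lie outside if list members were independent of each other. The members of a list share regulation, so this count is no test. Besides the erythroid, platelet and adipocyte lists, interferon-stimulated genes had a median of 0.35 in replicate 2 over replicate 1 (10 of 12 above 0), immediate early genes 0.20 (11 of 17), cytosolic ribosomal proteins 0.14 (37 of 38) and clock and output genes 0.10 (13 of 20). Extracellular matrix genes had a median of -0.10 (16 of 23 below 0), long and structural noncoding RNAs -0.13 (15 of 19) and fetal and load-responsive genes -0.09 (9 of 13), and all 3 medians turned above 0 with spike-in scaling. That scaling moved every log2 ratio up by 0.17, those of the random lists too, so these lists kept their place below the random lists. Medians of 0.05 to 0.10 above the random lists were found for sarcomere, respiratory chain, tricarboxylic acid cycle, ion channel, transcription factor and ventricular genes. The sarcomere, respiratory chain and tricarboxylic acid cycle lists no longer stood outside when random lists were matched on transcript length too, whereas the epicardial and mesothelial list (0.11) then did. With the second quantifier the endocardial and lymphatic (0.15) and the pericyte and smooth muscle (0.08) lists came to stand outside.

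**Figure D4:**
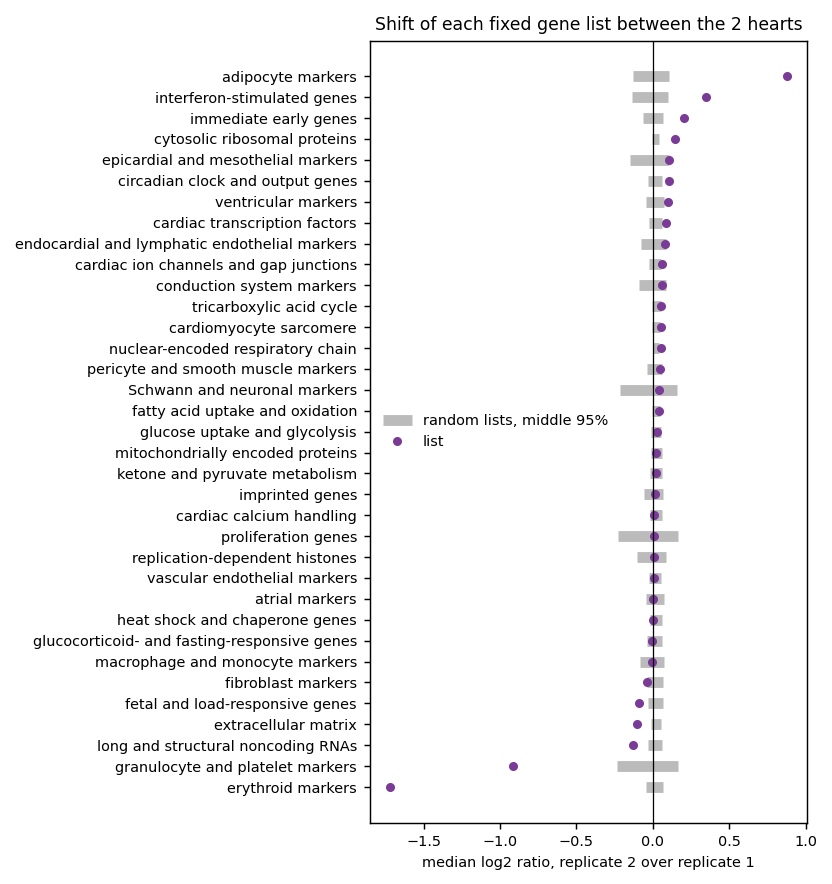
Median log2 ratio of replicate 2 over replicate 1 (x axis) of 35 fixed gene lists as points, with the middle 95% of 10000 random lists matched on mean expression as grey bars. Erythroid markers lie lowest at -1.72 and adipocyte markers highest at 0.88.

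The most abundant transcript of a gene was mostly the same in both hearts. Among 10281 genes with at least 2 annotated transcripts and 1 TPM in every table, the dominant transcript was the same in both mice for 88.9% with the gene-table quantifier and 87.3% with the second quantifier. Between quantifiers it was the same for 75.0% in replicate 1 and 75.7% in replicate 2. Of 32 fixed heart genes with alternative transcripts, 21 had the same dominant transcript in all 4 tables. They included Tpm1, with 97.0 ± 0.0667% of its TPM on Tpm1-205, the phosphate carrier Slc25a3, with 92.4 ± 0.324% on Slc25a3-206, titin (Ttn), with 36.6 ± 0.965% on Ttn-201, and Ldb3, with 71.7 ± 0.844% on Ldb3-203. For Tnnt2 the gene-table quantifier placed 64.8 ± 1.24% on Tnnt2-211 in both mice, whereas the second quantifier placed 36.2 ± 2.91% on Tnnt2-209. The dominant transcripts of Cacna1c, Ktn1, Fn1, Rbfox1, Mef2c and Mbnl1 also differed between quantifiers in both mice. Those of Pdlim5 and Pkm differed between quantifiers only in replicate 1. For Nebl the quantifiers gave Nebl-208 in replicate 1 and Nebl-202 in replicate 2.

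Levels correlated less between the quantifiers than between the mice. Pearson's r between quantifiers, across genes with at least 1 TPM in either, was 0.873 in replicate 1 and 0.875 in replicate 2, and across transcripts it was 0.560 and 0.557. Between mice, r across transcripts was 0.949 with the gene-table quantifier and 0.934 with the second. Of 13006 genes, 372 were at least 2-fold higher and 407 at least 2-fold lower with the second quantifier in both mice, on the log2(TPM + 1) scale, and 217 of the lower ones were pseudogenes. The genes named next were the 10 farthest apart among those at 10 TPM or more in the gene table, a limit that leaves out genes high only with the second quantifier. Rn7s1 and Rn7s2 went from 65350 ± 2526 to 0.720 ± 0.394 TPM and Rn7sk from 15091 ± 2083 to 0.780 ± 0.499. Both annotated entries of Rmrp, mt-Atp8, Gm12338 and Gm24265 went to 0, Gm10925, a nuclear copy of a mitochondrial gene, from 17364 ± 349 to 0.000391 ± 0.000532, and Rpph1 from 2550 ± 95.5 to 3.65 ± 0.618. Among fixed-list genes, Myl2 went from 8071 ± 621 to 17390 ± 1233 TPM, Gapdh from 1582 ± 99.0 to 3508 ± 190, Myh7 from 793 ± 92.4 to 1589 ± 187 and Cycs from 58.0 ± 2.23 to 657 ± 35.0. Myl2, Gapdh, Myh7 and Cycs were picked from 33 such genes after their values were seen. So was Gm28439, a pseudogene that went from 0 to 658 ± 78.3 TPM. Other levels given above that moved by over 1.5 times included those of Hba-a1 (to 8845 TPM), Hbb-bs (8451), Tnni3 (6243), Tnnt2 (6105), Cryab (1950.2), Cox6b1 (971) and Hist1h4d (2.42), and the medians of the histone list (2.42), the ketone and pyruvate list (230.5) and the conduction list (3.15).

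ERCC spike-in RNAs, added by the authors per the labels, took 0.547% of expected counts in replicate 1 (95% Wilson interval 0.545% to 0.550%) and 0.502% in replicate 2 (0.50% to 0.504%), a mean of 0.525 ± 0.0319%. Of 96 spike-ins, 63 had at least 1 count in both mice. Across the 43 with a mean count of at least 10, Pearson's r of log2 counts between mice was 0.998 and Spearman's rho 0.998. Relative to the spike-ins, replicate 2 had 1.13 times the TMM-scaled gene counts of replicate 1.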

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

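The count of genes 2-fold apart with both quantifiers was chosen after seeing the data. Depth limits low genes: the 2-fold genes higher in replicate 2 and in replicate 1 numbered 25 and 46, but 116 and 290 at a mean count of at least 10, 2571 and 3062 with no filter, and 5 and 17 at 200, where fewer or more low counts were tested. Spike-in scaling gave 43 higher in replicate 2, because it adds 0.17 to each log2 ratio. With both quantifiers 13 were higher in replicate 2; the cause was not tested. Total count scaling, DESeq2 size factors, the second quantifier and a prior of 5 kept both counts within 1.5 times. However, the calls made from the second quantifier's own counts shared only 11 of the 25 and 30 of the 46 genes. Detected genes numbered 7611 at 5 TPM, and 12224 to 12294 with 1 mouse left out. As shares of expected counts, mitochondrial genes with their copies took 32.7%, nuclear protein-coding genes 60.3%, and as a share of TPM the spike-ins took 0.843%, since TPM corrects for length. Against all genes of the table, most of them not detected, 35 lists lay in the top 2.5% of random lists instead of 19. The correlation of the mice was 0.966 with a pseudocount of 0.1, 0.995 with no filter and 0.991 with the second quantifier. Between quantifiers, r across transcripts was 0.330 with a pseudocount of 0.1 and 0.573 for transcripts of at least 200 bases, and r across genes was 0.770 with a pseudocount of 0.1. At 10 TPM the dominant transcript was the same in both mice for 92.9% and 92.2% of genes with the first and second quantifier, and between quantifiers for 74.1% and 74.6% in replicates 1 and 2. Where it was at least 1.5 times the next, these were 99.0%, 98.5%, 91.6% and 91.5%. The biological coefficient of variation ran from 6.62% without mitochondrial genes to 7.20% with no filter. The number of lists outside the random lists ran from 14 to 17 over 5 alternatives. Among these, DESeq2 size factors and spike-in scaling move all log2 ratios nearly alike, those of the random lists too, so they could hardly change this number. With the second quantifier, the log2 ratio of Hba-a1 to Hbb-bs (0.10) changed sign, and so did the ratios between mice of Gm45837 (1.61), Zc3h11a (-1.81), Gm49391 (0.57), Mrpl23 (0.07), Gm42688 and Gm14440, the last 2 close to 0. With spike-in scaling, the medians of the extracellular matrix (0.0708), fetal and load-responsive (0.0834) and long noncoding RNA (0.0453) lists did, for the same reason, and kept their place among the random lists. Of 1386 TPM values of named genes under alternatives, 656 moved by more than the SD between mice. Leaving out 1 of 2 mice always moves a mean by less than that SD, so values from this alternative could not be among the 656. No paired analysis was possible because there is 1 group.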

Other observations

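The tests of neutrophil, platelet and adipocyte genes used lists written after the differences between the mice had been seen, and the test of the summed hemoglobin counts was chosen after its values were seen. Beyond the lists described above, several single genes differed between the hearts by less than 2-fold or at low counts. The clock gene Per1 had a log2 ratio of replicate 2 over replicate 1 of 0.86 and Ciart, Cry1 and Per2 had 0.50, 0.46 and 0.45, while Arntl had -0.81 and Npas2 -0.34. Nr1d1, Dbp and Tef had -0.14, 0.24 and 0.10. Among glucocorticoid- and fasting-responsive genes, Cebpd (0.93), Sgk1 (0.49) and Tsc22d3 (0.42) were higher in replicate 2, whereas Mt2 (-0.69), Cdkn1a (-0.43) and Pdk4 (-0.31) were lower and Fkbp5 had -0.01. The smooth muscle genes Tagln, Acta2 and Myh11 had 0.57, 0.51 and 0.37. The nuclear RNAs Neat1 and Malat1 had -0.73 and -0.39, and the chaperones Hsph1, Hsp90aa1 and Hspa5 had -0.42, -0.37 and -0.31. The lymphocyte list had 955 counts in replicate 1 and 705 in replicate 2, with Igkc, Cd79b and Cd79a at log2 ratios of -1.17, -1.40 and -1.28.

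Most short RNAs that reached 10 TPM in the gene table were nearly missing from the second transcript table. This limit leaves out short RNAs high only in the second table, such as Gm22567 at 29.5 TPM. Of genes at 10 TPM or more in the gene table, all 69 shorter than 200 bases were at least 2-fold lower there, with a median log2 ratio of -5.49, and 60 of 65 with 200 to under 350 bases were, with a median of -4.76. Of 830 genes with 350 to under 1000 bases, 86 were, and of 4325 longer genes, 9 were, with medians of 0.31 and 0.19. The length classes were chosen after the data were seen.

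Red cell transcripts were higher in replicate 1: the summed counts of the 4 hemoglobin genes had a log2 ratio of -1.72, so reads shared between the copies do not account for the difference, and under all 4 scalings the median of the red cell list was at most -1.55, so a difference in library depth does not either. A candidate explanation is more blood in the replicate 1 tissue: the median log2 ratio of the platelet list was -1.69 with 11 of 11 tested genes lower in replicate 2, and it was -1.69 as well over the 9 tested genes that no fixed list holds. The mean count was under 50 for 8 of the 11, the summed counts of the list had a log2 ratio of only -0.79 (interval -0.90 to -0.68), against -1.68 for the summed red cell genes, and the 3 listed genes at a mean count of at least 50 (Pf4, Itgb3 and Ctla2a) had a median of -0.58, a limit chosen after the values were seen. Of the summed counts of the platelet list, 1738 and 1182 in replicates 1 and 2, Ctla2a alone held 867 and 701. Other platelet genes, not in the list, also had mean counts over 50 (Rgs18 -2.26, Ppbp -2.17, Tubb1 -1.89, Itga2b -1.56 and P2ry12 -1.52). They were picked here because they were at least 2-fold lower in replicate 2, so their ratios add no support. The median of the platelet list met the value set for more blood. More blood stays open, since this median and the summed counts of the list differ in size. Neutrophil genes had a median of -0.75 with 7 of 7 lower in replicate 2, between the values set for and against more blood; 7 of the 12 listed stand in fixed lists, and the counts were low, and no biological explanation was tested, since both mice belong to 1 group.

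Gm42418 and Lars2 were higher in replicate 1, where with the gene-table quantifier Lars2-209 held 100.1% of the Lars2 excess, and with the second quantifier it held 88.5%, under the 90% set beforehand, with 11.6% on the retained intron Lars2-205. The longest protein-coding transcript, Lars2-201, was not higher in replicate 1 with either quantifier (10.4 and 11.95 TPM, and 12.4 and 17.4 TPM), which argues against higher expression of the whole gene, although the share on a single transcript depends on the quantifier. Lars2 transcripts had 0 31-base words in common with Gm42418, CT010467.1 or Gm26917 on either strand, so reads shared by exact sequence between Lars2 and those features do not account for it, whereas CT010467.1 and Gm42418 had 1735 words in common on opposite strands. Less complete removal of ribosomal RNA in replicate 1 may be the reason and stays open. The summed 5S genes had 3.74 and 0 counts (log2 ratio -3.19, with a counting interval that includes 0), too few to decide. Gm26917, listed here with the ribosomal RNA features, stood at 5782 and 6042 TPM in replicates 1 and 2, with a log2 ratio of 0.03. Not every such feature was therefore higher in replicate 1. The 45S ribosomal RNA was not analysed here, and no biological explanation was tested.

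Adipocyte transcripts were higher in replicate 2. The summed counts of the fixed list without Lipe and Pnpla2, which heart muscle also uses, were 1240 and 2462, with a lower 95% counting bound of 0.66 on the log2 ratio, so counting error does not account for the difference. More adherent fat in the replicate 2 tissue may be the reason and cannot be told apart from a difference within the heart: 18 further adipocyte genes had a median log2 ratio of 0.21, above all matched random lists but under the 0.3 set beforehand, and 15 of 18 were higher. The summed counts of these further genes had a log2 ratio of only 0.088 (interval 0.066 to 0.110). The highest ratios were those of Adrb3 (1.88), Otop1 (1.69), Elovl6 (1.43) and Acvr1c (1.21), all at under 1 TPM. By TPM, Acvr1c was lower in replicate 2, at 0.15 against 0.24. Scd1 (0.73), Pnpla3 (0.63) and Fasn (0.56) followed. Pnpla3 was also under 1 TPM, with 7 and 13 counts and an interval of -0.77 to 2.23 that includes 0. Dgat2 and Kcnk3, at over 100 TPM in both hearts, had -0.01 and 0.02. No biological explanation was tested.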
